A study of Mus musculus with 6 samples.

How the data were processed

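ChIRP-seq libraries of Hoxc4-au were made from crosslinked, sonicated preadipocytes with an even and an odd pool of biotinylated probes, in 2 replicates with 1 input library each, and were built with a kit for small amounts of double-stranded DNA, per the labels' protocols. The 6 libraries gave 4 peak lists. FastQC, cutadapt, Bowtie and MACS2 and the mouse build mm9 are named in the submitters' processing notes; the version of the aligner and any filter on multiply mapping reads are not given in the sources used here. Peaks were called with MACS 2.1.1.20160309 on each captured library against the input of its replicate, per the file headers, with tags extended to 95 bp and no fragment model, a p cutoff of 5e-05, 1 tag kept per position, an effective genome size of 1.87e+09 and local background windows of 1 and 10 kb. The larger library of each pair was scaled to the smaller, and replicates were not pooled, per the file headers. These settings matter for the values: keeping 1 tag per position caps the fragments at a summit at 190 over both strands, and a fixed p cutoff calls weaker regions in deeper libraries.

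The deposited columns used were the signal (the fragment pileup at the summit, in fragments), the fold enrichment, and −log10 p-values and −log10 q-values. All are the caller's values for single peaks, as given by the authors. The fold is (pileup + 1) / (local background + 1), so it is lower than the plain ratio where the background is small. The genome-wide mean background was 0.200 and 0.208 fragments in replicate 1 (even, odd) and 0.585 and 0.520 in replicate 2. Folds over it are thus lowered more in replicate 1. The file headers announce that q-values were not calculated, but the deposited column holds values from 0.295 upward; 9.40% and 17.6% of replicate 1 peaks (even, odd) and 2.70% and 4.91% of replicate 2 peaks had a q above 0.05. Coordinates are 1-based mm9 positions from the lists.

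Depth per library was read from the file headers and is given with the results. Intervals on fragments are exact Poisson and on shares exact binomial (Clopper-Pearson), both at 95%, and cover counting error only; none is given for the highest counts, which the cap bounds. The local background of each peak was recovered from the deposited pileup and fold as (pileup + 1) / fold − 1. The lowest value found equals the genome-wide mean tag density in each list (0.200, 0.208, 0.585 and 0.520 fragments), and 40.2%, 43.1%, 10.8% and 19.2% of peaks gave a whole number of input fragments within 0.01. A background of 10 or more input fragments was called high.

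Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks were called shared when they overlapped by at least 1 bp. Overlaps of pairs of lists were tested, one-sided, against 10000 random circular shifts of the shorter list within each chromosome, over the span between the outermost peaks of all lists, because no chromosome lengths of the build were used here. Regions in all 4 lists were found by merging overlapping peaks and tested by shifting 3 lists against the fourth. On simulated lists of the real sizes with 20 planted sites, the test passed in 10 of 10 simulated pairs for each of the 6 comparisons, and in 0 of 10 without planted sites. The simulated sites in all 4 lists were recovered in 5 of 5 simulations. Simulated peaks were placed uniformly and independently, and fewer shifts were used than in the main tests. Lists whose peaks gather in the same regions were therefore not simulated. Proportions of fragments over the sites of a cluster were compared by permutation with 100000 resamples. Alternatives were another overlap rule, stricter thresholds, equal list lengths, fewer chromosomes, removal of the highest pileups, other random placements and each replicate alone.

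The tests of overlap, of sites in all lists and of peaks per chromosome, the correlations of folds, their alternatives and the rule for named sites were fixed before the data were examined. The share of peaks recurring in the other pool by strength, the proportions within the chromosome 15 cluster, the split of sites by background, the summit fragments relative to kept tags, the counts around the clusters and the counts per megabase were added after the data were seen. Peaks per chromosome were planned against chromosome lengths, and were tested against the span between the outermost peaks instead; a span shorter than its chromosome lowers the expected number; on chromosome X the span was 132 Mb. The rule names the 20 sites in all 4 lists with the highest value of their smallest fold, the 10 strongest sites shared by both pools of each replicate, and the strongest peak of each list by q. The high-background sites and the site at 17940402 on chromosome 16 lie outside the rule. So do the chromosome X cluster and the peak at 3109960 on chromosome 12 in the closing section. All of these were chosen after their values were seen. Gene annotation, gene lists, genomic distribution, a test of the HoxC locus and sequence content were also planned. They were not run, because the gene table used here is on GRCm38 and the peaks are on mm9, and positions were not converted between builds. With 2 replicates per pool, a two-sided exact permutation test between pools or between replicates cannot go below p = 0.333. Differences across libraries at single sites were not tested, and the tests, on peaks or fragments, describe these libraries.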

Results

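ChIRP-seq measures where an RNA sits on chromatin: crosslinked chromatin is captured with biotinylated DNA probes that tile the RNA, and the co-purified DNA is sequenced. Here the RNA was Hoxc4-au, captured from preadipocytes derived from the epididymal white fat of C57BL/6 mice, a visceral depot of male animals. The RNA carries the name of Hoxc4, a homeobox gene of the HoxC cluster. The probes were split into an even and an odd pool, and each pool was applied in 2 replicates, each with its own input library. This gave 6 libraries and 4 peak lists, because each captured library was compared with the input of its replicate. The labels do not say whether the replicates came from separate animals or cultures, so differences between them may be technical, and the tests on peaks and fragments describe these libraries alone. Fold enrichments are the peak caller's own values for each peak. The caller adds 1 to pileup and background, which lowers folds over a small background, more so in replicate 1. The design asks which regions are captured by both pools, and which of those regions recur between replicates. Separate probes against 1 RNA share that RNA but need not share off-target sequences. Either pool can also pull down the DNA of the gene the RNA is made from, so a peak there checks the capture.

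The replicates differed in depth. After duplicate reads were removed, the caller used 3934792 tags for the even and 4099230 for the odd pool of replicate 1, against 11514289 and 10231007 in replicate 2. Duplicates made up 47.6% and 40.2% of the tags in replicate 1, and 9.65% and 7.16% in replicate 2. The inputs kept 11924618 tags in replicate 1 and 12179777 in replicate 2. The even and odd lists held 234 and 204 peaks in replicate 1, and 5226 and 4157 peaks in replicate 2, which is 22.3 and 20.4 times as many.

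A cluster of 5 sites, each with a peak in all 4 lists, lay within 9.26 kb of chromosome 15 (mm9, 102857185 to 102866446). By the smaller fold of the pools, 4 of them led the sites shared by both pools in replicate 1, and all but the site at 102866013 were among the 10 highest in replicate 2. The site at 102857185 to 102858087 had the highest value, among sites in all 4 lists, of the smallest of its 4 folds, with a fold enrichment over input of 53.5 and 44.9 (even and odd pool) in replicate 1 and 55.5 and 54.3 in replicate 2, a mean of 52.0 ± 4.86 (SD over the 4 libraries). The site at 102858512 to 102858766 reached 71.4 and 63.3 in replicate 1 and 36.5 and 35.9 in replicate 2. The narrow site at 102862503 to 102862681 reached 29.9 and 29.6, then 18.5 and 17.9. The site at 102865109 to 102865646 was the strongest peak of both replicate 1 lists, with a fold of 123 for the even pool (162 fragments at the summit) and 138 for the odd pool (176 fragments). With tags of 95 bp and 1 tag kept per position, a summit holds at most 190 fragments, so high counts, and the folds and shares made from them, are lowered by this cap. In replicate 2 the same site had folds of 22.1 and 24.3. The last site, at 102866013 to 102866446, had folds of 57.9 and 81.1 in replicate 1 and of 5.88 and 10.5 in replicate 2. Within 100 kb on either side of the cluster, replicate 1 had no further peak, and replicate 2 had 3 further peaks with the even and 2 with the odd pool, with folds of 4.66 to 5.92. The HoxC cluster of the mouse lies on chromosome 15. Whether these sites fall inside it was not analysed here, because the gene table at hand is on another genome build. Capture of the RNA's own gene by both pools was not told apart from RNA on chromatin, and a position inside the cluster alone would not separate them. The 6 libraries are inputs and captures with the even and odd pools, with no capture by probes against another RNA. Capture common to both pools that does not depend on the RNA was thus not measured either.

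**Figure D1:**
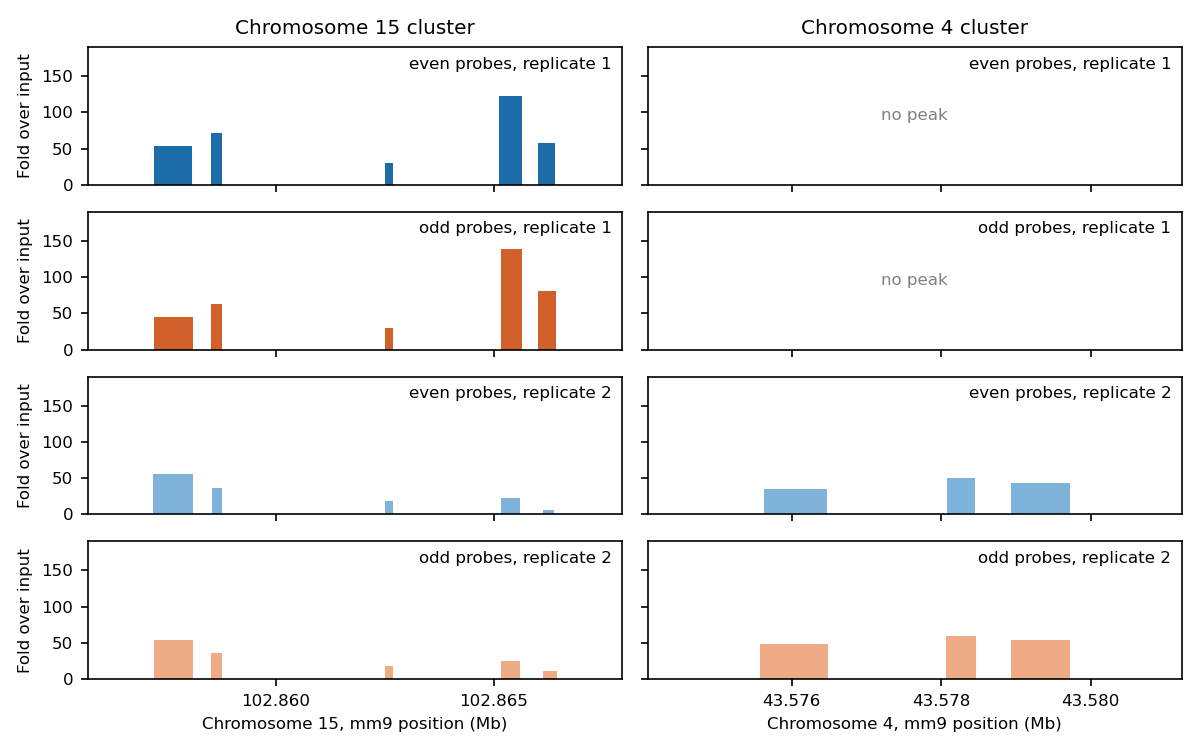
Peaks of the 4 lists over the chromosome 15 cluster (left) and a chromosome 4 cluster (right), with mm9 position in Mb on the x axis and fold enrichment over input on the y axis; each bar spans 1 peak and its height is the fold of that peak. The chromosome 15 cluster has 5 peaks in every list, with the site at 102865109 highest in both replicate 1 lists at folds of 123 and 138, and the chromosome 4 cluster has 3 peaks in both replicate 2 lists and none in replicate 1.

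The 5 chromosome 15 sites stood in different proportions to each other in the replicates, and no difference in proportions was detected between the pools of a replicate. The pair of sites on the right made up 32.9% and 15.4% of the cluster's summit fragments with the even pool of replicate 1, and 33.4% and 20.5% with the odd pool. In replicate 2 they made up 21.6% and 5.50% with the even pool and 22.7% and 7.80% with the odd pool. The site on the far left made up 24.9% and 23.0% in replicate 1 and 36.8% and 35.1% in replicate 2. A permutation test that reassigned fragments at random (100000 resamples, Benjamini-Hochberg adjustment over 6 pairs) gave an adjusted p of 0.278 between the pools of replicate 1 and 0.837 between those of replicate 2. For the even pool between replicates and for the odd pool between replicates the adjusted p was 2e-05. It was 0.000105 for the even pool of replicate 1 against the odd pool of replicate 2, and 2e-05 for the remaining pair. Each value of 2e-05 comes from an unadjusted permutation p of 1e-05, the smallest that 100000 resamples can give. These tests compare capped counts of 1 library with 1 library, so they set a difference against counting error alone and not against variation between replicates. Fragments that pass a duplicate filter need not be independent molecules. The order of sites does not depend on the cap: 102865109 held more fragments than 102857185 in replicate 1 (162 and 176 against 123 and 121) and fewer in replicate 2 (63 and 64 against 107 and 99). Relative to kept tags, summit fragments were more numerous in replicate 1 at all 5 sites, for example 41.2 and 42.9 per 1e+06 tags against 5.47 and 6.26 at 102865109.

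The pools shared a larger part of their peaks in replicate 1 than in replicate 2. In replicate 1, 115 of 234 even-pool peaks overlapped an odd-pool peak by at least 1 bp (49.1%, exact 95% interval 42.6 to 55.7), and 112 of 204 odd-pool peaks overlapped an even-pool peak (54.9%, 47.8 to 61.9). In replicate 2 the shares were 290 of 5226 (5.55%, 4.94 to 6.20) and 291 of 4157 (7.0%, 6.24 to 7.82). Random circular shifts of the shorter list within each chromosome gave a mean of 0.0559 overlapping peaks in replicate 1 and 2.44 in replicate 2, and at most 3 and 10. The one-sided p was 0.0001 for both replicates, the smallest that 10000 shifts can give. Both lists of a replicate were called against the same input, so part of the excess may come from that input. With all lists cut to their 204 strongest peaks by q, the even-pool share was 54.9% in replicate 1 and 31.4% in replicate 2. Among peaks with a −log10 q of 5 or more, the odd-pool share was 90.8% and 38.7%.

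The strength of a peak went with its recurrence in the other pool. Of the peaks with a −log10 q of 10 or more, 66 of 75 even-pool and 55 of 55 odd-pool peaks of replicate 1 were also called with the other pool, and in replicate 2, 41 of 45 and 30 of 30 were. Of the replicate 2 peaks with a −log10 q under 2, 3.26% of even-pool and 4.74% of odd-pool peaks recurred, with intervals of 2.41 to 4.29 and 3.68 to 5.99. Between 3 and 5, the shares were 4.98% and 6.75% in replicate 2, against 32.7% and 47.8% in replicate 1. The weak peaks dominated replicate 2: only 5.15% and 3.73% of its peaks had a −log10 q of 5 or more, compared with 51.3% and 42.6% in replicate 1. The median peak of replicate 2 held 7 fragments at its summit, and 79.8% of even-pool and 65.9% of odd-pool peaks had an implied background at the caller's genome-wide mean (within 0.005 fragments).

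**Figure D2:**
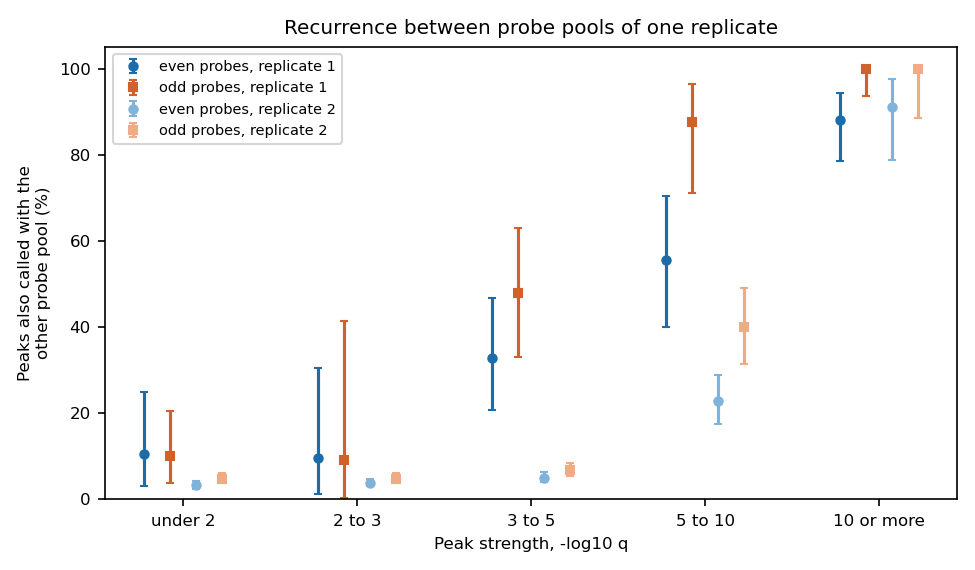
Share of peaks (y axis, percent) that overlap a peak of the other probe pool in the same replicate, by peak strength as −log10 q (x axis), for the 4 lists; points are shares and bars are exact 95% binomial intervals. Replicate 2 stays under 7% up to a −log10 q of 5, and at 10 or more every list reaches at least 88.0%.

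Across replicates, between 17.1% and 24.5% of replicate 1 peaks overlapped a peak of replicate 2. The even lists shared 40 of the 234 replicate 1 peaks, and the odd lists shared 50 of 204. The crossed pairs, which share neither a probe pool nor an input, gave 46 of 234 (19.7%, 14.8 to 25.3) for even probes in replicate 1 with odd probes in replicate 2, and 47 of 204 (23.0%, 17.4 to 29.4) for the reverse. Chance placement gave means of 0.103 to 0.145 peaks for these 4 pairs, with an adjusted one-sided p of 0.0001 for all 6 pairs. Across shared peaks, which are not independent replicates, log2 folds ranked alike between pools in replicate 1 (Pearson r = 0.96, Spearman rho = 0.91, 115 matched peaks) and less so in replicate 2 (r = 0.84, rho = 0.61, 295 matched peaks). Between replicates rho lay between 0.71 and 0.86, and with −log10 q in place of fold it was lower, from 0.13 for the even lists to 0.54 for the odd lists. The matched peaks include some over a high background, where folds can be low in every list (2.12 to 4.11 at the 6 such sites in all 4 lists). Without high-background peaks the even lists shared 28 and the odd lists 41 replicate 1 peaks. The correlation of folds without them was not computed.

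Merging all lists gave 9344 regions, of which 29 held a peak of every list and 8966 a peak of 1 list. None of 10000 random placements gave a region in all 4 lists (one-sided permutation p = 0.0001, the smallest they can give). The number was 17 among peaks with a −log10 q of 5 or more, 19 among those with a fold of 5 or more and 18 without the highest 1% of pileups. Of the 29 sites, 23 stood over a low implied background, a median of at most 2.5 input fragments, and 21 of these 23 had a higher mean fold in replicate 1 than in replicate 2. The median of this mean fold over the 23 sites was 22.7 in replicate 1 and 9.02 in replicate 2. Some of the 21 had a higher fold in replicate 1 with 1 pool and a lower one with the other. These include the chromosome 6 pair and the chromosome 11 site at 95444916 described below. Relative to kept tags, summit fragments were more numerous in replicate 1 with both pools at 22 of the 23 sites. The choice of sites favours this direction, because a call at the lower depth of replicate 1 needs more fragments per kept tag. Outside chromosome 15, the highest was a 589 bp site on chromosome X (103382016 to 103382604), with folds of 41.7, 48.8, 27.8 and 35.5 in the even and odd pools of replicate 1 and then of replicate 2, a mean of 38.4 ± 8.96 (SD, 4 libraries). A 173 bp site on chromosome 14 (104736121 to 104736293) had folds of 40.0 and 31.5 in replicate 1 and 11.4 and 13.8 in replicate 2. The site on chromosome 17 at 4626161 to 4626640 had 40.0 and 29.0, then 7.57 and 9.87. The chromosome 2 site at 16604658 to 16604821 had 32.3 and 26.8, then 8.22 and 11.4. The chromosome 9 site at 70653929 to 70654102 had 28.6 and 23.8, then 12.0 and 7.90.

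Other sites of the 20 highest had mean folds of at most 16.0. A pair of neighbouring sites on chromosome 6 (121438038 to 121438370 and 121438437 to 121438753) had mean folds of 9.28 ± 1.05 and 8.05 ± 1.54 (SD, 4 libraries), and were higher in replicate 1 by 1.06 and 1.08 times in the mean fold of its pools and by 2.17 and 2.33 times in mean summit fragments relative to kept tags. The chromosome 11 site at 95444916 to 95445211 had 7.47 ± 0.86, and was higher in replicate 1 by 1.11 and 2.44 times on these scales. In fold, the pools went in opposite directions at each of these sites. The even pool was lower in replicate 1 at 121438038 (8.33 against 8.83) and at 95444916 (7.11 against 7.57). The odd pool was higher at both (10.8 against 9.21, and 8.61 against 6.58). At 121438437 the even pool was higher (10.0 against 6.94) and the odd pool lower (6.70 against 8.55). Sites on chromosome 1 (12634788 to 12634988), chromosome 2 (125973572 to 125973734), chromosome 5 (114623056 to 114623220) and chromosome 18 (65587075 to 65587234) had mean folds of 15.2, 13.2, 15.1 and 16.0, and those on chromosome 6 (131327504 to 131327664), chromosome 9 (62456332 to 62456507) and chromosome 7 (52879008 to 52879165) had 14.0, 11 and 14.7. All 7 were higher in replicate 1, by 1.63 to 3.40 times in fold and by 4.04 to 6.12 times relative to kept tags. Among the other 3 low-background sites, that on chromosome 16 (17940402 to 17940712) had folds of 4.51 and 6.70 in replicate 1 and 13.9 and 8.55 in replicate 2. Per 1e+06 kept tags it held 1.27 and 1.95 summit fragments in replicate 1 and 1.82 and 1.17 in replicate 2, with opposite directions in the pools.

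The remaining 6 sites stood over a median of 35.5 to 43.5 input fragments and had folds of 2.12 to 4.11. Of these, 4 lay within 5.68 kb of chromosome 17 (39980106 to 39985784), 1 on chromosome 11 (108872983 to 108873384) and 1 on chromosome 3 (5860594 to 5860812). The SD of the fold over the 4 libraries ranged from 0.13 at 39980106 to 39980683 (mean 2.86) to 0.52 at 39983412 to 39983646 (mean 2.52), where folds were 3.22 and 2.58 in replicate 1 and 2.14 and 2.12 in replicate 2. Relative to kept tags, summit fragments were more numerous in replicate 1 with both pools at 1 of the 6 and less numerous with both at 4.

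**Figure D3:**
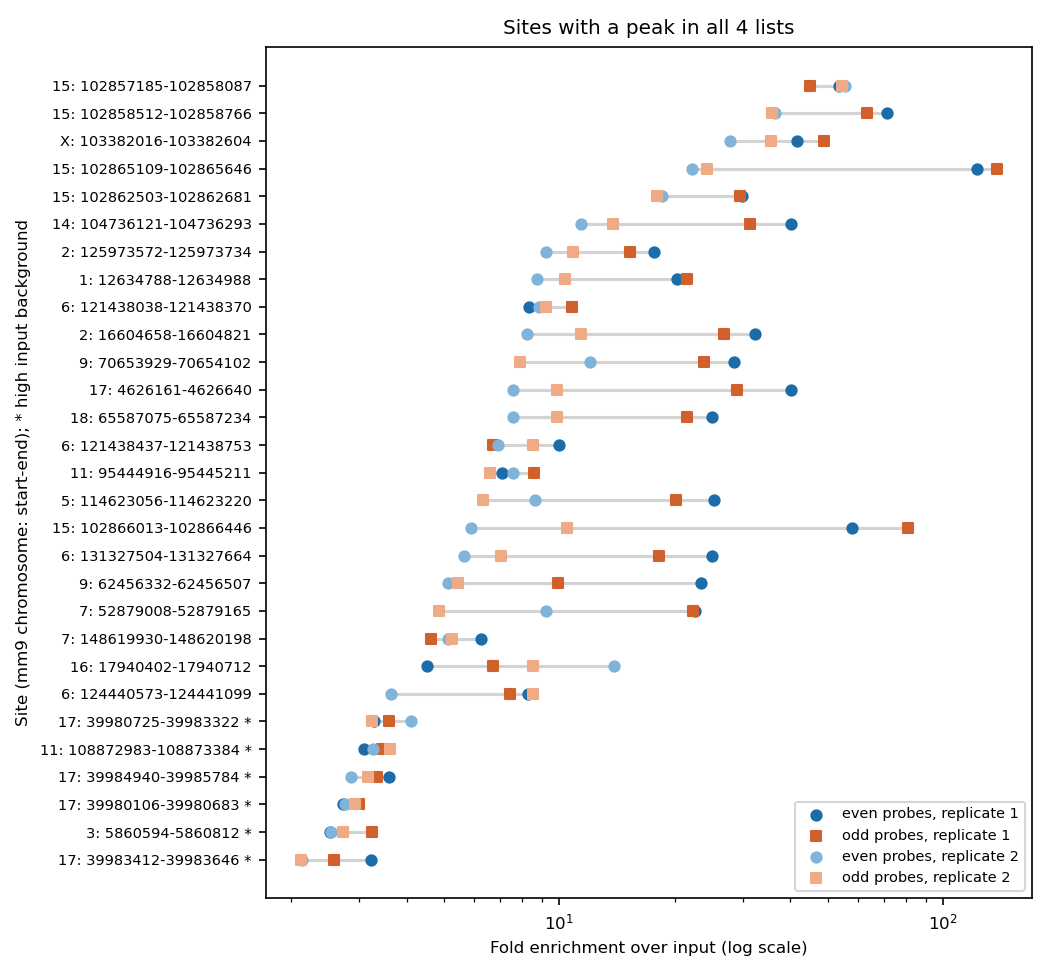
Fold enrichment over input (x axis, log scale) of the 29 sites with a peak in all 4 lists, 1 row per site in order of the smallest of its 4 folds; circles are even and squares odd probes, dark for replicate 1 and light for replicate 2, and asterisks mark the 6 sites over a high input background. Of the 23 unmarked sites 21 have the higher mean fold in replicate 1, some of them with 1 pool only. The 6 marked sites lie between 2.12 and 4.11 in every library.

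Sites shared by both pools of a replicate often lacked a peak in the other replicate. Replicate 1 had 111 such regions, of which 38 (34.2%) overlapped a replicate 2 peak and 73 did not. Of the 10 with the highest smaller fold in replicate 1, only the site on chromosome 11 at 25000095 to 25000257 had no replicate 2 peak, with folds of 30 and 26.5. The regions shared by both pools of replicate 1 were narrow, with a median width of 160 bp (interquartile range 152 to 224). Replicate 2 had 286 such regions, of which 42 (14.7%) overlapped a replicate 1 peak.

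A second cluster appeared in replicate 2 alone, within 4.14 kb of chromosome 4 (43575577 to 43579719). Its 3 sites had folds of 35.3 and 48.5 (43575577 to 43576481), 50.5 and 59.9 (43578070 to 43578461), and 43.6 and 53.4 (43578938 to 43579719) with the even and odd pools. The last was the strongest peak of both replicate 2 lists by q, with 125 and 142 fragments, under the same cap of 190. Neither list of replicate 1 had a peak in this cluster. The 10 strongest shared sites of replicate 2 otherwise held the chromosome X and 14 sites, 4 of the chromosome 15 sites, and a site on chromosome 16 (69604247 to 69604504) with folds of 17.7 and 17.1 and no peak in replicate 1.

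Peaks of replicate 2 were spread unevenly over the chromosomes. Chromosome 11 held 504 of 5218 even-pool and 400 of 4148 odd-pool peaks, 2.06 and 2.05 times the number its span would give. Chromosome X held 20 and 15, which is 0.07 times that number with either pool. By exact binomial tests with Benjamini-Hochberg adjustment over 20 chromosomes, 10 chromosomes were higher and 9 lower with the even pool, and 8 higher and 9 lower with the odd pool. In replicate 1 chromosome 9 alone passed the exact binomial test with either pool, at 2.28 and 2.39 times (adjusted p = 0.0027 and 0.0033), and it did not when peaks within 10 kb were counted once. Chromosome X held 5 and 3 peaks there, 0.41 and 0.28 times the number from its span, with adjusted p of 0.24 and 0.072 by the exact test. The difference between replicates was not tested. Peaks are not independent where they cluster, and the expected numbers take the span between the outermost peaks as the chromosome length. The expected numbers also assume equal copies of all chromosomes, whereas cells of male animals carry fewer copies of X than of an autosome. How far this lowers the counts on chromosome X was not tested.

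**Figure D4:**
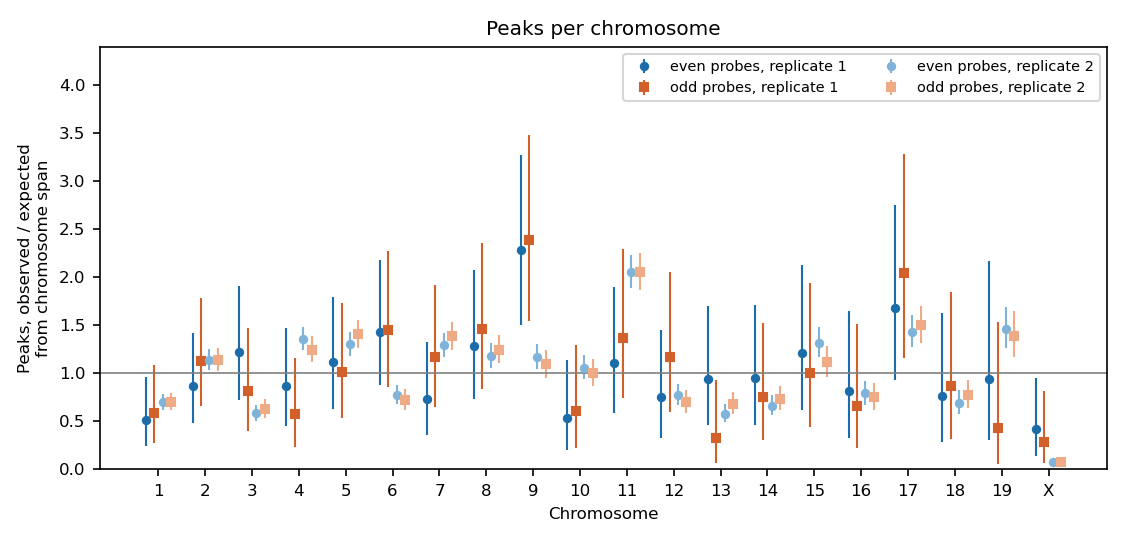
Number of peaks per chromosome (x axis) over the number expected from the chromosome's span (y axis) for the 4 lists, with exact 95% binomial intervals as bars and a grey line at 1. In replicate 2 both pools lie at about 2.05 on chromosome 11 and at 0.07 on chromosome X. The expected number does not allow for the copy number of chromosome X.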

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

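The alternative that left out high-background peaks and the one that left out the chromosome 15 cluster were chosen after seeing the data; the others were planned. All 6 pairwise overlaps stayed above chance placement under each of the 10 alternatives run for each, with a permutation p of 0.0001. The share of the shorter list lay between 50% and 90.8% in replicate 1 and between 4.19% and 38.7% in replicate 2, highest at a −log10 q of at least 5 in both (each replicate was tested without the other). Across replicates it lay between 9.91% and 27.6%. The lists cut to equal length gave 31.4% in replicate 2. The 29 sites in all 4 lists became 17 at a −log10 q of at least 5, 19 at a fold of at least 5 and 18 without the highest 1% of pileups, and 23 without high background. They were 112 to 286 with 1 replicate left out, because only 2 lists then have to share a site: 286 without replicate 1 and 112 without replicate 2, counted over the lists left (111 in the merge of all 4). The rank correlation of folds moved beyond its 95% interval in 9 of 24 cases. At a −log10 q of at least 5 it was 0.87 between the pools of replicate 1, 0.79 between those of replicate 2 and 0.59 between the even lists. With 50% reciprocal overlap it was 0.77 between the pools of replicate 2. With −log10 q in place of fold it was 0.84 between the pools of replicate 1, 0.13 between the even lists, 0.54 between the odd lists, and 0.24 and 0.43 for the crossed pairs (even probes of replicate 1 first); the cause was not tested. Counting peaks within 10 kb once left 0 chromosomes past the exact binomial test in either replicate 1 list (1 and 2 at an unadjusted p under 0.05), in place of 1 each. No paired analysis was possible because each result is an overlap, a count or a correlation of whole lists and sets no group of libraries against another; a difference between pools at single sites, paired by replicate, was not tested. How depth limits the replicate 1 calls was not tested beyond the chromosome 4 cluster; the fewest summit fragments of a called peak were 4 in replicate 1 and 5 in replicate 2. Alternatives on promoter definition and on the threshold, reach, placement and sites of the gene tests were not run, for want of an annotation of the build.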

Other observations

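The test of high background for the strong replicate 1 peaks and the test of the shared input by draws were chosen before their results were seen; the tests of depth, of single-pool capture, of few fragments and of the input as the whole cause were chosen after. Among the chromosome 15 sites, 3 had edges that differed little between libraries: at 102857185 to 102858087 the start varied by 6 bp and the end by 5 bp over the 4 lists, at 102858512 to 102858766 by 10 and 7 bp, and at 102862503 to 102862681 by 8 and 8 bp. At 102865109 to 102865646 they varied by 46 and 51 bp, and at 102866013 to 102866446 by 108 and 73 bp. Over all regions shared by both pools, the median difference between pools was 5 bp at the start and 4 bp at the end in replicate 1, against 36.5 and 44 bp in replicate 2. In replicate 2 both pools also shared 9 sites within 14.4 kb of chromosome X (166421481 to 166435929), with smaller folds of 2.48 to 7.65. On the mitochondrial chromosome replicate 1 had 3 peaks with the even and 1 with the odd pool, and replicate 2 had 0.

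Replicate 2 peaks gathered in the same megabases with both pools where they shared no position: without overlapping peaks, even-pool and odd-pool peaks in 2529 bins of 1 Mb, which are not independent replicates, had a Spearman rho of 0.62 (Pearson r = 0.78), above the highest of 1000 rotations of the bins (0.20). At a −log10 q of 3 to 5, 32.7% and 47.8% of replicate 1 peaks (median 7 fragments) recurred in the other pool. Of replicate 2 peaks (median 8), 4.98% and 6.75% did. The prediction for few fragments at the summit as the whole cause was thus not met. Some of those replicate 1 peaks stood over a high background, such as 77 input fragments at 3109960 on chromosome 12. A comparison between replicates does not settle the cause within replicate 2. Even-pool peaks of replicate 1, called on another input, followed those of replicate 2 with a rho of 0.152. That lay below the central 95% of 1000 draws of 190 odd-pool peaks of replicate 2 (0.218 to 0.281). A part played by the input common to both pools predicts this. The draws share the replicate as well as the input, so they cannot single out the input. Most replicate 2 peaks (79.8% even, 65.9% odd) had an implied background at the genome-wide mean. The rho of 0.152 still exceeded the highest of its rotations, 0.0723, so the prediction for the input as the whole cause was not met. That cannot exclude the input, because the rotations remove every regional pattern, including any that the inputs of the replicates share. Other differences between the replicates, which the draws also contain, and regional properties of the chromatin were not tested.

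Strong replicate 1 peaks were often absent from replicate 2: of 130 peaks with a −log10 q of 10 or more in the even and odd lists, 87 overlapped no replicate 2 peak. A region called with both pools counts once in each list. The tables argue against fewer tags in replicate 2, which kept 2.93 (even) and 2.5 (odd) times as many as replicate 1. Kept tags do not measure the strength of capture, however. At 22 of the 23 low-background sites in all 4 lists, summit fragments per kept tag were more numerous in replicate 1 with both pools. The choice of sites favours that direction, because each also had to be called at the lower depth of replicate 1. The fewest summit fragments of a called peak were 4 there and 5 in replicate 2. The absent peaks held a median of 15 (even) and 14 (odd) fragments in replicate 1. Whether weaker enrichment in replicate 2 left them uncalled was not tested. Of the absent peaks, 45 of 54 with the even and 33 of 33 with the odd pool (89.7% together) overlapped a peak of the other pool. That argues against off-target capture by the probes of 1 pool for those peaks. It is no separate test, because it follows from the recurrence of strong replicate 1 peaks given above (66 of 75 and 55 of 55). The tables argue against sequence of high input background, since 11.5% had 10 or more implied fragments in the replicate 1 input. Properties of the replicate 1 libraries, of which 47.6% and 40.2% of tags were duplicates, and differences between the cells of the replicates stay open and were not tested.

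The chromosome 4 cluster was the converse, strong with both pools in replicate 2 and without a peak in replicate 1. At replicate 1 depth its sites would be expected to hold 27.0 to 56.9 fragments, with 95% Poisson limits down to 21.4, above the medians of 9.5 and 8 in peaks called there, which argues against depth. The background of these sites in the replicate 1 input was not analysed here. Whether the cells, the capture or the libraries of the replicates differed was not tested, because each replicate has 1 library per pool.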
